A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

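Total RNA of budding yeast (Saccharomyces cerevisiae) was measured on 12 1-colour Affymetrix yeast arrays, with biotin as the label per the labels. The 12 arrays form 4 groups of 3: a rap1 temperature-sensitive (ts) mutant with its own wild-type control, and an abf1 ts mutant with its own wild-type control. Per the labels, cells grew at 25 C and were shifted to 37 C for 1 h before RNA was isolated. The labels number the arrays 1 to 3 in each group and do not say whether equal numbers mark separate cultures, so p-values measure only the spread between these samples, which may be technical.

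The deposited values are probe set intensity values on a linear scale, made by the authors with MAS5 per the submitters' processing notes. The MAS5 version, its settings and detection calls are not given in the sources used here. The mean signal of each array without its lowest and highest 2% of probe sets lay between 1500.7 and 1501.3, so the deposited intensity values had been scaled to a common mean per array. Median signals of the non-control probe sets ran from 390.4 to 598.3. The number of arrays limits the precision, and 2 arrays shared at most 36 identical probe set values, so no array was a copy of another.

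The table held 9335 probe sets, of which 60 were controls. Of the others, 6504 named 1 gene, 328 named several genes and 2443 were unnamed here. All 5923 gene identifiers of the platform annotation were found in a gene table of assembly R64, and 0 symbols had to be updated. That table was used for names, gene lengths and the order of genes, and no coordinates are given because no genome build is named for the arrays. Each gene or set of genes was represented by its probe set of highest mean, and features whose mean log2 value lay under the 20th percentile were left out. This left 4687 features of 5859, with a mean of at least 8.16 on the log2 scale. Of these, 4543 named 1 gene and 144 named several genes, and no gene is named from the latter.

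Tests were run on log2(signal + 13), where 13 is the 10th percentile of all non-control values, and fold changes are on that scale, which understates the change of dim genes. limma 3.58.1 in R 4.3.3 fitted the means of the 4 groups, with a variance trend on intensity and Benjamini-Hochberg adjustment over all features. A feature was called at an adjusted p under 0.05. The contrasts were each mutant against its wild type, the difference of the 2 mutant effects, and the wild types against each other. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. There were 29 lists, and a list needed at least 3 features for the test. The list of telomere-proximal genes took the 10 outermost protein-coding genes of each chromosome end by gene order, a choice made after seeing the data because distances in bases could not be used. Tests that need promoter sequence were not run, since no genome was used here.

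Equal replicate numbers were checked for pairing by a rule fixed in advance, although the correlations and the calls of the fits were first printed together. Deviations from group means were correlated across features between arrays of the same number. Within each series these correlations ran from 0.25 to 0.824, above the minimum of 0.1 set in advance, and all 12 arrays were closest to the array of their own number. By that rule the numbers pair the arrays, from the data and not from a statement in the labels, and values with the replicate number within each series as a block are given wherever the block changes a call.

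Signal ratios of the 3' and 5' control probe sets of ACT1, SPT15 and SRB4 were compared between groups with a 2-sided exact permutation test, whose smallest p for 3 against 3 arrays is 0.1. Named genes followed a rule: RAP1, ABF1 and the auxotrophic markers, up to 8 genes per direction with the largest fold change among called genes whose groups did not overlap, and up to 2 called members of each list past its test. The rule also took up to 4 genes called in both mutants per direction. The contrasts with their tests, both fits, this rule and the lists other than the telomere-proximal one were fixed before the data were examined. The use of the rule on the blocked fit, the tests that the closing section names as chosen later, the naming of every gene called without the block, and a block shared by all 12 arrays were added after seeing the data. The alternatives tried were 3 other scalings, other offsets and filters, other ways to join probe sets, fits on 6 arrays, a fit without the variance trend, a fold of at least 2, and each array left out in turn.

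The fits were tested on simulated data in which 50 of 4687 genes were changed for each fold size. With a true log2 change of 2 in either direction, the fit without a block recovered between 76% and 80% of the changed genes in the simulated rap1 and abf1 comparisons. With a true change of 1 it recovered between 2% and 10%, with 0 false calls. The blocked fit recovered 98% to 100% and 60% to 86%, with 11 false calls in the rap1 and 7 in the abf1 simulation. The simulated arrays took their replicate-number effects and residual spread from the blocked fit, with noise drawn independently for each gene. The simulation therefore favoured the block in advance and cannot decide whether the block suits the real arrays.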

Results

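Rap1 and Abf1 are essential DNA-binding proteins of budding yeast that occupy many promoters. Rap1 also binds telomeres and the silent mating loci. Genome-wide RNA levels were measured in ts mutants of each factor, which lose DNA binding at 37 C, and in a separate wild-type control for each mutant. The comparison of each mutant with its wild type asks which RNAs change after 1 h without that factor's binding. There were 3 arrays per group and 12 arrays in all. The first principal component of the arrays carried 33.15% of the variance, of which 51.6% lay between the 4 groups and 44.3% between the replicate numbers. The second component carried 26.46%, of which 53.1% lay between the numbers and 14.8% between the groups.

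**Figure D1:**
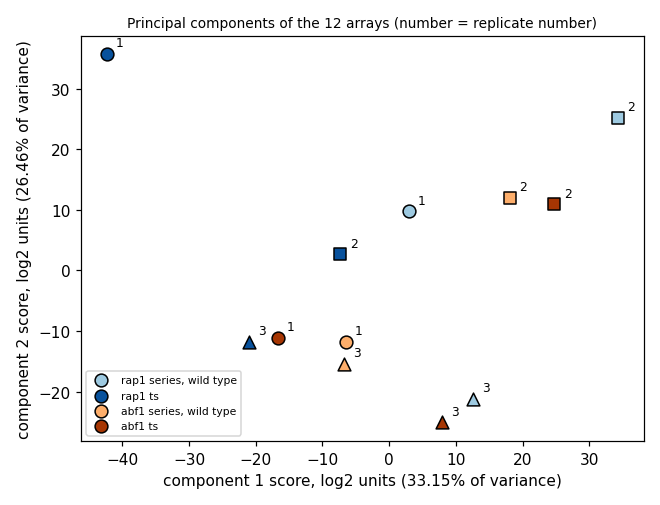
Each point is an array, placed by its scores on the first 2 principal components of log2(signal + 13) over 4687 features. Colour gives the group and the marker and digit give the replicate number; the rap1 ts array 1 lies apart from the other 11 arrays.

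Signal along control transcripts differed between the rap1 groups. ACT1, the actin gene, had a 3' to 5' signal ratio with a geometric mean of 6.75 in the wild type and 30.1 in rap1 ts, and the 2 sets of 3 arrays did not overlap (exact permutation p = 0.1, the smallest possible). For SPT15, which encodes the TATA-binding protein, the means were 4.98 and 15.9 (exact p = 0.1), with 56.9, 8.91 and 7.87 in the 3 ts arrays, and for SRB4, a Mediator subunit gene, 46.4 and 228 (exact p = 0.2). In the abf1 series the ACT1 means were 12.02 in the wild type and 7.93 in the mutant (exact p = 0.6). The wild-type array 2 of the rap1 series had the lowest median signal, 390.4, and the highest 98th percentile, 19399, of the 12 arrays.

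**Figure D2:**
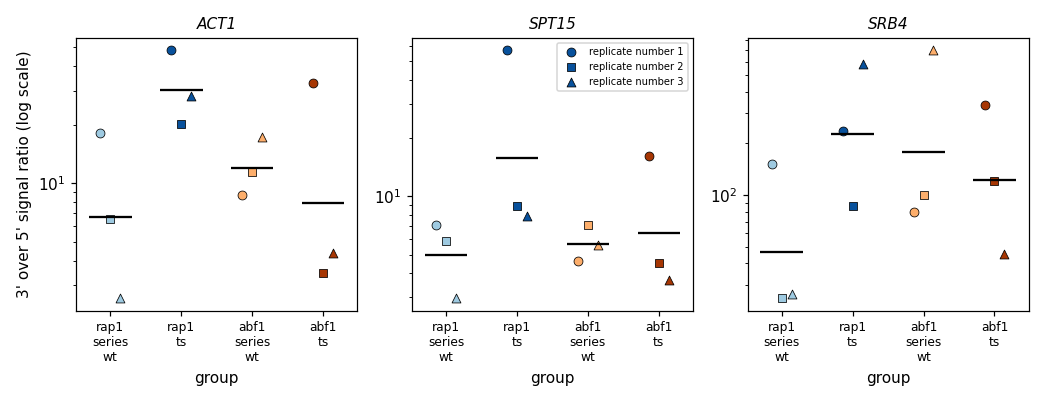
Ratio of 3' to 5' probe set signal on a log axis for 3 control transcripts, with 1 point per array, a marker per replicate number and a black line at each group's geometric mean (n = 3). For ACT1 the rap1 ts arrays lie between 20.1 and 48.4 and their wild-type arrays between 2.56 and 18.2.

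In rap1 ts OPI3, which encodes a methyltransferase of phosphatidylcholine synthesis, fell 14.3-fold, from a signal of 3094 ± 1802 (SD, n = 3) to 195.1 ± 89.5 (log2 fold change -3.84, SE 0.49, limma adjusted p = 0.00637). The ribosomal protein gene RPS7B fell 6.47-fold, from 9039 ± 2885 to 1383 ± 418 (log2 fold change -2.69, SE 0.31, adjusted p = 0.00361). RPL7A, RPS1A and RPL14B, also ribosomal protein genes, fell with log2 fold changes of -2.13, -1.98 and -1.19 (limma adjusted p = 0.00838, 0.0147 and 0.0207). They were called in 18, 16 and 10 of 19 other settings. RPL7A was not called with the mean over its probe sets (adjusted p = 0.0724). The probe sets of RPL14B and ALG3 are of types shared by similar sequences, so their values may include a close relative. Of the 2 genes that rose without a block, HIS3, a histidine synthesis gene, rose more, from 1046 ± 235 to 3269 ± 533 (log2 fold change 1.64, SE 0.26, adjusted p = 0.0147). UBX3, which encodes a UBX-domain protein, rose by a log2 fold change of 1.35 (SE 0.24, adjusted p = 0.0259).

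In all, 17 of 4687 features fell and 2 rose in rap1 ts, each at least 2-fold, by limma without a block. At an unadjusted p under 0.05, 438 were lower and 605 higher, 1043 in all, against 234 expected by chance over both directions. Among the genes that fell were ARG1 (argininosuccinate synthetase, log2 fold change -2.28), PRO1 (the first enzyme of proline synthesis, -1.49) and the vacuolar amino acid transporter gene AVT4 (-1.88). GSC2, a catalytic subunit gene of glucan synthase, fell by 2.22, and CIS3, a cell wall protein gene, fell by 1.61. The others were the homeobox repressor gene YHP1 (-2.27), the calponin-like SCP1 (-1.98), YMR027W (-1.73), KSH1 of the early secretory pathway (-1.53), the mannosyltransferase gene ALG3 (-1.45), SVS1 (-1.35) and the TFIIH subunit gene SSL1 (-1.23). In each of these genes all 3 pairs of arrays moved the same way, and the 3 ts values lay on 1 side of the 3 wild-type values. RAP1 itself differed little, with a log2 fold change of -0.12 (SE 0.30, adjusted p = 0.842), and ABF1 had -0.46 (SE 0.62, adjusted p = 0.679). The number of genes that fell was 6 without wild-type array 1, 8 without wild-type array 2, 8 without ts array 1 and 10 without ts array 3. The number that rose was 0 without wild-type array 1, wild-type array 2 or ts array 3, and 1 without wild-type array 3 or ts array 1.

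**Figure D3:**
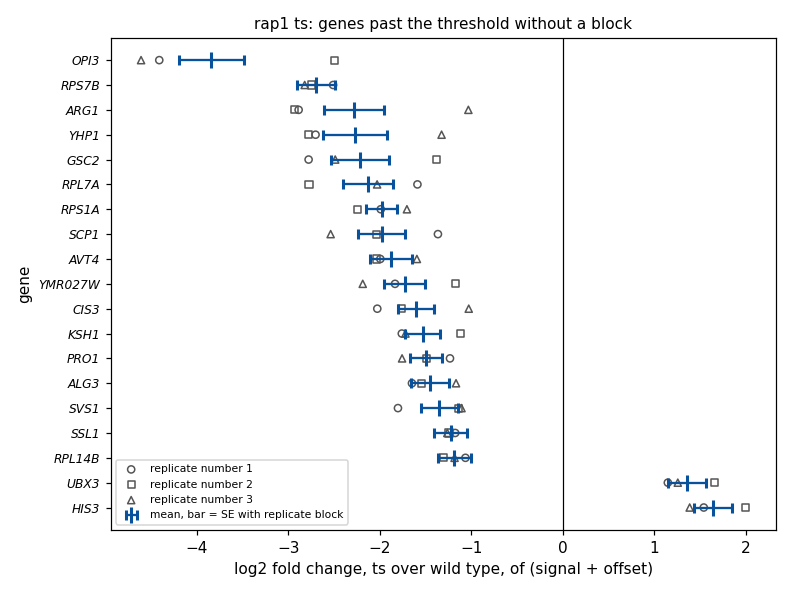
Log2 fold change of rap1 ts over wild type for the 19 genes called without a block, with open markers for the 3 pairs of equal replicate number, a vertical tick for the mean and a bar for its SE under the replicate block. OPI3 lies lowest at -3.84 and HIS3 highest at 1.64, and no marker crosses 0.

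With the replicate number as a block, 470 features fell and 701 rose in rap1 ts, 250 of each at least 2-fold, and these included all 19 found without the block. Under quantile scaling the split was 614 lower and 597 higher, under median centring 594 and 558, and under centring outside the ribosome and glycolysis lists 649 and 540. Leaving out the replicate pair 1, 2 or 3 gave 205, 530 and 286 lower and 495, 427 and 342 higher. The genes of largest fall with the block included MET6, the methionine synthase gene (log2 fold change -2.99, blocked SE 0.27, adjusted p = 0.000927), and MOG1, a nuclear transport gene (-2.54, blocked SE 0.31, adjusted p = 0.00321). TOS1, TOS6, STR3 and SIM1 had -2.48, -2.41, -2.39 and -2.36 and fell with the block. ARO10, a decarboxylase gene of amino acid breakdown, rose most among genes whose groups did not overlap (2.17, blocked SE 0.27, adjusted p = 0.00321). YNL146C-A (1.98), IRC18 (1.90), the cytochrome c gene CYC7 (1.83), the aldehyde dehydrogenase gene ALD3 (1.81), TDA6 (1.78), PET191 of cytochrome oxidase assembly (1.76) and CMI8 (1.75) rose as well. For these block-only genes the adjusted p without the block lay between 0.0593 for ARO10 and 0.254 for TDA6. With a block over all arrays 931 of the 1171 were also called, and TDA6 was not (adjusted p = 0.0936). Groups did not overlap for 26.52% of features in rap1 ts, where chance gives 10% for unpaired arrays, a share that does not allow for the pairing of these arrays. The median log2 fold change of all genes was 0.088 as deposited, 0.021 under quantile scaling and -0.015 under centring outside those lists.

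Cytosolic ribosomal protein genes as a list lay lower in rap1 ts: 97 of 117 features were below 0, with a median log2 fold change of -0.23 (limma camera adjusted p = 1.68e-10; adjusted p = 0.578 with an estimated correlation). Of its members 4 fell over all features, 16 adjusted over the list alone, and 30 with the replicate block. The 3 pairs differed, with medians of 0.096, -0.627 and -0.198, and without wild-type array 2 the median was -0.03 and the list no longer passed (adjusted p = 0.0712; 9.5e-23 to 0.578 over the 20 other settings). The genes of sulfur and methionine metabolism had a median of -1.30, with 15 of 15 features below 0 (camera adjusted p = 2.18e-07; adjusted p = 0.469 with an estimated correlation). None was called over all features without the block, 8 fell adjusted over the list alone, and 11 fell with the block. MET6 and STR3 led them. Amino acid biosynthesis genes had a median of -0.51 (34 of 40 below 0; camera adjusted p = 8.67e-09; adjusted p = 0.145 with an estimated correlation). In that list 1 gene fell over all features, ARG1, 13 fell adjusted over the list alone, and 15 fell with the block, ARG3 of arginine synthesis among them at -2.05. In these same arrays the ACT1 ratio stood at 30.1 against 6.75 in the wild type.

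The cell wall integrity list had a median of -0.84 in rap1 ts, with 9 of 14 features below 0 (camera adjusted p = 0.00147; adjusted p = 0.487 with an estimated correlation), of which GSC2 and CIS3 fell, 6 adjusted over the list alone. Its pair medians were -1.245, 0.154 and -0.86, and its median was -0.34 without ts array 1 and -0.46 without wild-type array 3. The phosphate regulon had a median of -0.66, with 8 of 8 features below 0 (camera adjusted p = 0.00147; adjusted p = 0.145 with an estimated correlation). No member was called without the block, 4 fell adjusted over the list alone, and 4 with the block, the phosphatase genes PHO5 (-1.44) and PHO8 (-0.73) among them. Glycolysis and fermentation genes had a median of -0.36, with 18 of 21 features below 0 (camera adjusted p = 0.000115; adjusted p = 0.544 with an estimated correlation). None was called without the block, 3 fell adjusted over the list alone, and 7 fell with the block. ENO1, an enolase gene, had -2.12 and HXK2, a hexokinase gene, -2.10, both called with the block. Translation factors had a median of -0.36 (camera adjusted p = 0.00176; adjusted p = 0.431 with an estimated correlation), with 0 called, 3 adjusted over the list alone, and 6 with the block, including CAM1 (-1.30) and GCD11 (-1.22). Without wild-type array 2 the glycolysis list (median -0.07) and the translation factors (-0.11) no longer passed. Ergosterol synthesis genes had a median of -0.25 (camera adjusted p = 0.0153; adjusted p = 0.631 with an estimated correlation), with 1 lower adjusted over the list alone. With the block 7 fell, led by ERG13 (-1.84) and ERG25 (-1.61), and the list did not pass without ts array 1 (median -0.02). The 5 core histone features had a median of -0.28 (camera adjusted p = 0.0363; adjusted p = 0.431 with an estimated correlation), 1 of them lower adjusted over the list alone, and the H2B gene HTB2 fell with the block (-2.06). Subtelomeric gene families had a median of -0.39, with 21 of 26 below 0 (camera adjusted p = 0.0363; adjusted p = 0.709 with an estimated correlation), 0 called, 0 adjusted over the list alone, and 3 lower and 1 higher with the block. COS6 (-1.06) and PAU13 (-0.58) were among the 3. PAU13 has a probe set shared by similar sequences and was not called with a block over all arrays (adjusted p = 0.0694). The histones and the subtelomeric families did not pass without wild-type array 1 (-0.26 and -0.36), wild-type array 2 (-0.22 and -0.28) or ts array 3 (-0.19 and -0.28). The histone call also ended under the 3 other scalings, the 50th percentile filter, on 6 arrays and with a block over all arrays (camera adjusted p from 0.0501 to 0.0953). The subtelomeric call also ended under quantile scaling, centring outside the ribosome and glycolysis lists and the 50th percentile filter (0.0521 to 0.183), and the ergosterol call under quantile scaling (0.0638). In the arrays of all these lists the SPT15 ratios were 56.9, 8.91 and 7.87 in rap1 ts and 7.08, 5.87 and 2.97 in the wild type.

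Mitochondrial ribosomal protein genes lay higher in rap1 ts: 63 of 65 features were above 0, with a median of 0.78 (camera adjusted p = 2.73e-10; adjusted p = 0.578 with an estimated correlation). None was called over all features or adjusted over the list alone without the block, and 38 rose with it, including MRPS5 (log2 fold change 1.57, blocked SE 0.26, adjusted p = 0.00659) and MRPL27 (1.37). Pair medians were 0.441, 1.439 and 0.419, and without wild-type array 2 the median was 0.46. Heat shock protein genes had a median of 0.55, with 23 of 27 features above 0 (camera adjusted p = 0.0153; adjusted p = 0.679 with an estimated correlation). None was called without the block, 1 rose adjusted over the list alone, and 6 rose with the block, among them the membrane protein gene HSP30 (1.98) and the Hsp70 gene SSA4 (1.64). The pair medians of this list were -0.041, 1.319 and 0.212, and without wild-type array 2 its median was 0.23 and it did not pass, nor did it without wild-type array 1 (0.47), ts array 2 (0.37) or ts array 3 (0.34), or with the 50th percentile filter (camera adjusted p = 0.0501). These higher lists, too, were measured in arrays with the raised ACT1 ratio, and the rap1 wild type had medians of -0.50 and -0.74 for them relative to the abf1 wild type. Ribosome biogenesis genes (median 0.22), general stress-induced genes (0.34), the respiratory chain and ATP synthase (0.32), the proteasome (0.27) and telomere-proximal genes (-0.04) did not pass in rap1 ts, with camera adjusted p of 0.259, 0.143, 0.0913, 0.0549 and 0.441. Without ts array 1 the general stress (0.97), respiratory (0.55) and proteasome (0.41) lists passed, and so they did without wild-type array 3 (0.66, 0.49 and 0.39), and ribosome biogenesis passed without ts array 2 (0.42). The proteasome also passed under quantile scaling (0.22) and with no filter (0.27). With an estimated correlation over all arrays the general stress, respiratory and proteasome lists each had camera adjusted p = 0.731, and ribosome biogenesis 0.758. The 3 features of meiosis and sporulation (median 0.99) did not pass (camera adjusted p = 0.0560; adjusted p = 0.431 with an estimated correlation). They passed under the 3 other scalings and without wild-type array 3. The a-specific mating genes (0.51, 5 of 6 above 0) did not pass either (camera adjusted p = 0.0956; adjusted p = 0.631 with an estimated correlation). They passed with no filter, over every probe set and without wild-type array 2 or ts array 1. Genes that earlier reports tied to Abf1 sites had a median of -0.20 and did not pass without a block (camera adjusted p = 0.0646). The list passed with the block (camera adjusted p = 0.0466; adjusted p = 0.559 with an estimated correlation), over every non-control probe set (-0.27) and without wild-type array 3 (-0.35). With the block RPL3 (-1.20) and RPC40 (-1.01), a subunit gene of RNA polymerases I and III, fell.

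**Figure D4:**
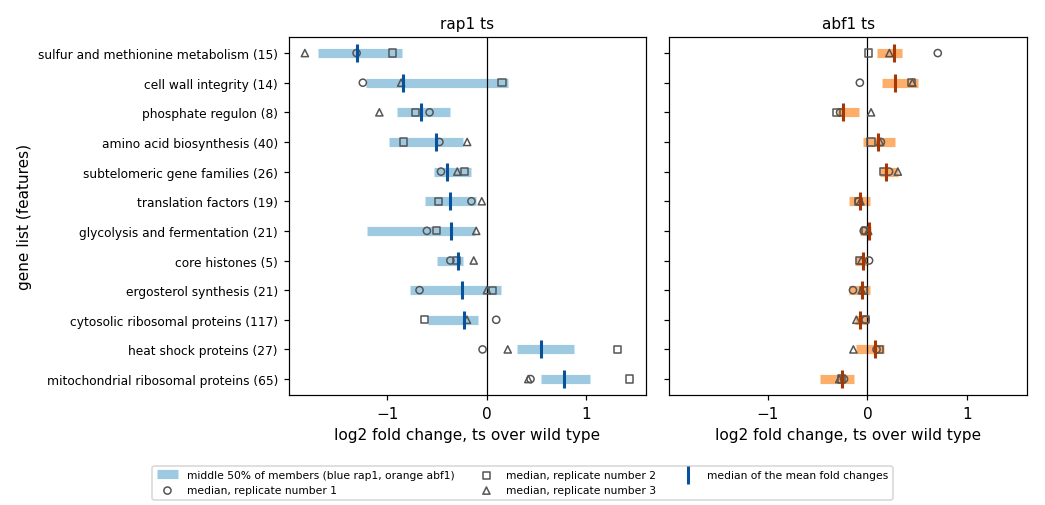
Median log2 fold change of the 12 lists past the preset camera test in rap1 ts, shown for rap1 ts (left) and abf1 ts (right), with bars over the middle 50% of members and open markers for the medians of the 3 pairs. Sulfur and methionine metabolism lies at -1.30 in rap1 ts and 0.27 in abf1 ts, and mitochondrial ribosomal proteins at 0.78 and -0.25.

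In abf1 ts 2 genes fell. NIT3, which encodes a nitrilase family protein, fell 4.02-fold, from a signal of 4857 ± 794 (SD, n = 3) to 1227 ± 366 (log2 fold change -2.01, SE 0.27, limma adjusted p = 0.0195). POP8, a subunit gene of RNase P and RNase MRP, fell 6.84-fold, from 3058 ± 1179 to 440.4 ± 194.2 (log2 fold change -2.77, SE 0.40, adjusted p = 0.0229). Both were lower in 3 of 3 pairs. ABF1 itself had a higher signal in the mutant, 3176 ± 1427 against 1009 ± 410 (log2 fold change 1.61, SE 0.62, adjusted p = 1.00 and 0.102 with the block), higher in 3 of 3 pairs without passing the test. RAP1 had a log2 fold change of -0.33 (SE 0.30) in this mutant.

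Of 4687 features 2 fell and 0 rose in abf1 ts by limma without a block. At an unadjusted p under 0.05 there were 132 lower and 13 higher, 145 in all, fewer than the 234 expected by chance over both directions. With the replicate block 10 fell and 0 rose, including both genes above. The proline synthesis gene PRO3 fell with the block by 2.62 (blocked SE 0.43, adjusted p = 0.0494) and EMC3, of a membrane protein complex of the endoplasmic reticulum, by 1.93 (blocked SE 0.30, adjusted p = 0.0419). SSF2 of ribosome biogenesis had -1.72, the dipeptidase gene DUG1 -1.54, YKL069W -1.39, the pyrophosphatase gene IPP1 -1.34 and YPR148C -1.30, each called with the block. The remaining gene, KAP120 of nuclear transport, had -1.34 and was named after its value was seen. With a block over all arrays 8 of these 10 were also called, and DUG1 (adjusted p = 0.0695) and KAP120 were not. The SSF2 probe set is of a type shared by similar sequences, so its value may include a close relative. No gene was called without wild-type array 1, 2 or 3 or without ts array 1 or 3, 10 fell without ts array 2, and 0 were called under median centring or centring outside the ribosome and glycolysis lists. Under quantile scaling with the block 16 fell and 2 rose. With the block, 0 fell without pair 1 or pair 3 and 12 without pair 2. Groups did not overlap for 7.62% of features, where chance gives 10% for unpaired arrays.

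**Figure D5:**
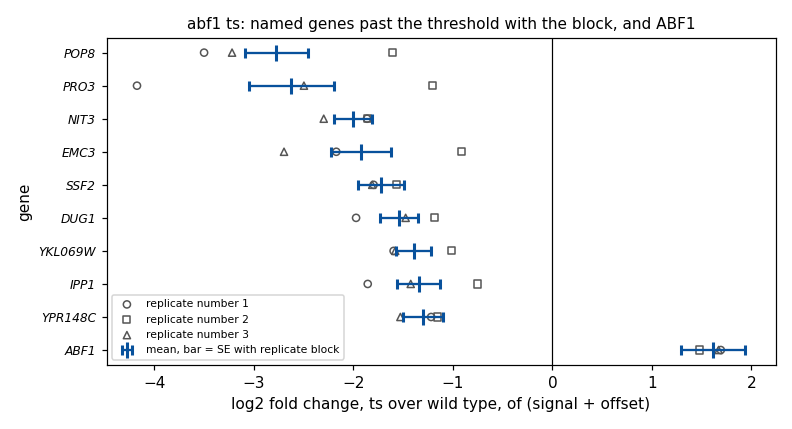
Log2 fold change of abf1 ts over wild type for the 9 named genes called with the replicate block and for ABF1, with open markers for the 3 pairs, a tick for the mean and a bar for its SE under the block. POP8 lies lowest at -2.77, and ABF1 lies at 1.61 with all 3 pairs above 0 but was not called.

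Among the lists in abf1 ts, mitochondrial ribosomal protein genes had a median log2 fold change of -0.25, with 60 of 65 features below 0 (camera adjusted p = 4.79e-07; adjusted p = 0.814 with an estimated correlation). Ribosome biogenesis genes had a median of -0.24, with 70 of 76 below 0 (camera adjusted p = 9.51e-07; adjusted p = 0.640 with an estimated correlation). The subtelomeric gene families lay the other way, with a median of 0.19 and 26 of 26 above 0 (camera adjusted p = 2.05e-05; adjusted p = 0.640 with an estimated correlation). Telomere-proximal genes had a median of 0.12, with 94 of 137 above 0 (camera adjusted p = 0.000648; adjusted p = 0.640 with an estimated correlation), and the cell wall integrity list had 0.28 (camera adjusted p = 0.00232; adjusted p = 0.640 with an estimated correlation). Amino acid biosynthesis (0.11), general stress-induced genes (0.14) and sulfur and methionine metabolism (0.27) passed narrowly, at camera adjusted p of 0.0420, 0.0452 and 0.0484, and had adjusted p = 0.640, 0.814 and 0.814 with an estimated correlation. In none of these 8 lists was a member called over all features, with or without the block, and 0 passed adjusted over the list alone, apart from 5 mitochondrial ribosomal protein genes with the block. The mitochondrial ribosomal list did not pass without wild-type array 1 (median -0.11), nor the subtelomeric families and telomere-proximal genes without wild-type array 3 (-0.05 and 0.03) or ts array 2 (0.02 and 0.10), nor the cell wall list without wild-type array 2 (0.12). Amino acid biosynthesis did not pass without wild-type array 1 (0.11), wild-type array 3 (0.06) or ts array 2 (0.08), general stress without those same arrays (-0.06, 0.14 and -0.11), and sulfur metabolism without wild-type array 1 (-0.12), wild-type array 2 (0.18) or ts array 3 (-0.34). The amino acid call also ended under median centring, centring outside the ribosome and glycolysis lists, no filter and every probe set (camera adjusted p from 0.0893 to 0.245). The general stress call ended under quantile scaling, no filter, means over probe sets and every probe set (0.0528 to 0.181), and the sulfur call under these 4 settings, 4 times the offset and 6 arrays (0.0502 to 0.275). The cytosolic ribosomal proteins (-0.07, camera adjusted p = 0.296) and the genes that earlier reports tied to Abf1 sites (-0.15, camera adjusted p = 0.154) did not pass. Both did without ts array 2 (-0.09 and -0.13), and the former also without wild-type array 3 (-0.13), on 6 arrays and over every probe set. With an estimated correlation over all arrays the 2 lists had camera adjusted p = 0.954 and 0.640. With the block the proteasome (0.10) and G1/S cell cycle genes (-0.28) also passed, at camera adjusted p of 0.0324 and 0.0323, and had adjusted p = 0.809 and 0.799 with an estimated correlation.

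No gene was called in both mutants in the same direction, and the overlap expected of independent lists was 0.007 genes lower (Fisher's exact p = 1). With the replicate block 0 genes fell in both against 1.003 expected (Fisher's exact p = 0.612), and YPR148C fell in abf1 ts and rose in rap1 ts (0.68, blocked adjusted p = 0.0366). With so few calls in abf1 ts, neither overlap test could have shown fewer shared genes than independent lists give. The fold changes of the 2 mutants correlated at r = -0.073 (rho = -0.076) across 4687 genes, which are not independent replicates, and 47.2% had the same sign. The test of the difference of the 2 effects called 0 genes without the block, with a smallest adjusted p of 0.0969. At an unadjusted p under 0.05, 211 were lower and 385 higher, 596 in all, against 234 expected by chance over both directions. With the block, the effect was lower in rap1 ts than in abf1 ts for 135 features and higher for 291. The split was 187 and 249 under quantile scaling, 241 and 335 under median centring, and 278 and 244 under centring outside the ribosome and glycolysis lists. Without pair 1, 2 or 3 of the rap1 series it was 40 and 85, 306 and 326, and 7 and 2, and without pair 1, 2 or 3 of the abf1 series 106 and 182, 18 and 40, and 0 and 0.

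The auxotrophic markers, genes often deleted or replaced in laboratory strains, were examined in every comparison. HIS3 rose in rap1 ts, as given above, and had 0.59 in abf1 ts (adjusted p = 1.00). With the block MET17 (-1.69), ADE2 (-1.11) and LEU2 (-0.95) fell in rap1 ts. URA3 (-0.39), ADE1 (-0.24), TRP1 (0.04) and LYS2 (0.13) were not called in rap1 ts, and no marker was called in abf1 ts. Of the 8 markers, 3 were lower and 1 higher in rap1 ts adjusted over the list alone. Which markers each strain carries was not tested, so a difference in strain genotype stays open for these genes.

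The 2 wild types were compared to show how far arrays differ without a ts mutation. No gene was called between them by limma without a block. At an unadjusted p under 0.05, 138 were lower and 18 higher in the rap1 wild type, 156 in all, against 234 expected by chance over both directions. The block within series cannot compare the wild types. With a block over all arrays 0 were called, but the smallest adjusted p was 0.0535. In that fit 426 were lower and 98 higher at an unadjusted p under 0.05. Groups did not overlap for 9.22% of features, where chance gives 10% for unpaired arrays. Heat shock protein genes had a median of -0.74 in the rap1 wild type relative to the abf1 wild type. Of their features 27 of 27 lay below 0 (camera adjusted p = 1.73e-10; adjusted p = 0.461 with an estimated correlation). General stress-induced genes had -0.96 with 25 of 25 below 0 (camera adjusted p = 6.72e-09; adjusted p = 0.461 with an estimated correlation), and mitochondrial ribosomal protein genes -0.50 with 65 of 65 below 0 (camera adjusted p = 1.73e-10; adjusted p = 0.671 with an estimated correlation). Adjusted over the list alone, 4 heat shock, 4 general stress and 0 mitochondrial ribosomal genes were lower, and 12, 5 and 0 with a block over all arrays. Some lists that were lower in rap1 ts lay higher in the rap1 wild type. They were cytosolic ribosomal proteins (0.11), glycolysis (0.15), translation factors (0.16), amino acid biosynthesis (0.05) and subtelomeric families (0.25). Their camera adjusted p ran from 1.75e-09 to 0.0173, and from 0.461 to 0.671 with an estimated correlation. The other lists lower in rap1 ts did not pass between the wild types. In all, 13 lists passed the preset test between the wild types and none with an estimated correlation.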

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

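The tests of wild-type array 2, of the ACT1 ratio by replicate number, of the named differences with a block over all arrays and of the numbers across the series were chosen only after the result was seen. The results here were picked out because the effect of rap1 ts differed from that of abf1 ts. With the replicate block within each series 135 genes had a lower and 291 a higher effect in rap1 ts, and with a block over all arrays 86 and 187. Without a block 0 genes passed (smallest adjusted p 0.0969).

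For 10 lists the difference of the effects passed limma's camera at the preset correlation, and none passed with an estimated correlation. Median differences were -0.18 for cytosolic ribosomal proteins (adjusted p = 0.689 with an estimated correlation), 1.07 for mitochondrial ribosomal proteins (0.494), -0.39 for glycolysis (0.504), -0.19 for translation factors (0.494) and 0.47 for ribosome biogenesis (0.707). They were -0.62 for amino acid biosynthesis (0.224), -1.57 for sulfur and methionine metabolism (0.477), -0.70 for subtelomeric families (0.504), -1.05 for the cell wall list (0.477) and -0.17 for telomere-proximal genes (0.494). With the replicate block heat shock proteins (0.58) and the phosphate regulon (-0.36) passed as well (camera adjusted p = 0.0265 and 0.0295; adjusted p = 0.768 and 0.506 with an estimated correlation).

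Among named genes the difference passed for 47 with the replicate block within series, at adjusted p from 0.0116 to 0.0441, and for none without it. With a block over all arrays 42 of these passed, and STR3, ERG13, DUG1, HSP30 and CYC7 did not (adjusted p from 0.0545 to 0.144). Most named genes had been chosen for a call and a large change in 1 mutant, which is part of this difference. The choice itself therefore favoured a pass. Over all 4687 features the difference passed for 426 with the block within series. The effect was lower in rap1 ts for OPI3 (-4.43), MET6 (-3.60), TOS1 (-2.82), ARG1 (-2.81), MOG1 (-2.78), SIM1 (-2.50), RPS7B (-2.47), STR3 (-2.46), GSC2 (-2.37), HXK2 (-2.23), SCP1 (-2.17), MET17 (-2.09), YHP1 (-2.09), ABF1 (-2.07), RPL7A (-2.05) and ERG13 (-2.05). It was also lower for ERG25 (-1.85), KSH1 (-1.85), YMR027W (-1.79), AVT4 (-1.75), LEU2 (-1.65), RPS1A (-1.65), PHO5 (-1.59), CIS3 (-1.498), ALG3 (-1.30), RPL14B (-1.29), PRO1 (-1.24), SSL1 (-1.21), RPC40 (-1.19) and SVS1 (-1.18). The effect was higher in rap1 ts for CMI8 (3.25), POP8 (2.96), CYC7 (2.43), ARO10 (2.31), MRPL27 (2.26), SSF2 (2.16), IRC18 (2.08), YPR148C (1.98), PET191 (1.94), EMC3 (1.87), NIT3 (1.84), HSP30 (1.83), MRPS5 (1.71), YNL146C-A (1.68), YKL069W (1.52), UBX3 (1.503) and DUG1 (1.12). For POP8, SSF2, YPR148C, EMC3, NIT3, YKL069W and DUG1 the difference came mainly from falls in abf1 ts. CMI8 had 1.75 in rap1 ts and -1.50 in abf1 ts. For ABF1 the difference came mainly from 1.61 in abf1 ts, against -0.46 in rap1 ts, and neither was called. Its mean signal was 414 in the rap1 wild type and 1009 in the abf1 wild type, a difference not called. PAU13 (-0.88) was lower in every pair of the rap1 series and higher in every pair of the abf1 series, and its difference did not pass the blocked test (adjusted p = 0.0584).

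Cytosolic ribosomal protein genes lay lower in rap1 ts. RNA with more 3' bias would lower them no more than genes of the same length, yet their median of -0.23 lay below the 2.5th percentile, -0.017, of 10000 random sets matched on gene length. Against sets matched on mean expression that percentile was -0.21 and 37 of 10000 sets were as low, a narrow margin for compression of bright probe sets. Both kinds of random set drew genes independently, while the list's estimated correlation was 0.57. Their percentiles are therefore too narrow, and neither comparison excludes its explanation. Under 3 other scalings the median nearest 0 was -0.10, under quantile scaling, with camera adjusted p of at most 5.78e-05, against adjusted p = 0.578 with an estimated correlation as deposited. Without wild-type array 2 it was -0.028 (adjusted p = 0.0712), so that 1 array could account for the call and the pattern stays open. The rap1 wild type itself had a median of 0.11 relative to the abf1 wild type for this list, with 98 of 117 features above 0. A high control therefore stays open for part of the fall.

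Mitochondrial ribosomal protein genes lay higher in rap1 ts. Their median of 0.78 exceeded the matching upper percentile of length-matched sets, 0.28, and 0 of 10000 sets were as high. The median nearest 0 under other scalings was 0.63, and without wild-type array 2 it was 0.46 (camera adjusted p = 4.72e-06), a lower value, against adjusted p = 0.578 with an estimated correlation over all arrays. The rap1 wild type itself had a median of -0.50 relative to the abf1 wild type for this list, so a low control stays open for part of the shift. Scaling and that array did not account for the whole shift at the preset correlation. The random sets drew genes independently, while the list's estimated correlation was 0.69, so their percentiles are too narrow to exclude length. Their own median of 0.09 shows only that the list moved further than genes of its length typically did. A difference in growth between the cultures was not tested.

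Arrays of the same number deviated together. Of the 6 ways to assign the abf1 numbers only 1, the labelled one, gave so high a mean correlation with the rap1 series (0.387, next 0.081), which is too few ways to decide on a shared day or batch. In the rap1 series the ACT1 ratio of the paired arrays deviated with the same sign for 3 of 3 numbers, as in 2 of the 6 ways to assign them, so RNA quality stays open there. In the abf1 series the signs matched for 1 of 3 numbers, as in 4 of the 6 ways, so this test decides nothing there either. No biological explanation was tested.

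The counts were repeated after other splits of the same arrays. In rap1 ts without a block 1 of 10 splits, the labelled one, called 19 genes and the next highest 12, and in abf1 ts 1 of 10 called 2 and the next 0. With the replicate block 1 of 4 splits called 1171 in rap1 ts and 1 of 4 called 10 in abf1 ts, and the others 0. These splits are too few for a share under 0.05. Between the wild types 10 of 10 splits called 0. For the difference without a block the labelled split called 0, and the highest of 100 splits called 7. With a labelled count of 0 in both cases no split could call fewer, so neither comparison tests chance. With the block 2 of 32 called at least 426, a share above 0.05. The highest, 667, kept the 3 rap1 pairs as labelled and swapped 1 abf1 pair, so it carries the rap1 effect and these splits leave chance undecided for that count.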

How the results depend on the processing

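The block over all arrays, the alternatives under the block and the outermost 5 or 20 genes were chosen only after the result was seen. Promoter motif tests and telomere distances in bases were not run. Signal over background limits dim genes, which the offset understates, and each setting that leaves out an array rests on 2 arrays in that group. Of the alternative values of counts 196 stayed within 1.5 times the reported count and 78 did not.

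In rap1 ts 17 fell and 2 rose. Falls were 28 under quantile scaling, 28 under median centring, 32 under centring outside the ribosome and glycolysis lists, 30 over every non-control probe set and 3 on 6 arrays. Rises were 1 with the filter at the 50th percentile, 7 over every probe set and 0 on 6 arrays. Leaving out an array gave 6 to 22 lower and 0 to 2 higher. In abf1 ts the 2 falls became 0 under median centring, under centring outside those lists and on 6 arrays, and 0 to 10 with an array left out. The difference, 0 genes, became 4 lower under quantile scaling, 1 under median centring and 1 under centring outside those lists, and 0 to 2 lower and 0 to 2 higher with an array left out.

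With the replicate block rap1 ts had 470 lower and 701 higher, and 373 and 567 with a block over all arrays. A fold of at least 2 left 250 and 250, 6 arrays gave 224 and 256, and leaving out a pair gave 205 to 530 lower and 342 to 495 higher. In abf1 ts both blocks gave 10 lower, 8 of them shared. Within series it was 16 lower and 2 higher under quantile scaling, 27 and 2 under median centring, 18 and 2 under centring outside those lists, 5 lower with no filter, 5 over every probe set, 2 higher on 6 arrays, and 0 to 12 lower without a pair. The blocked difference, 135 lower and 291 higher, was 86 and 187 with a block over all arrays. Lower counts were 241 under median centring, 278 under centring outside those lists and 89 without the intensity trend, and 186 were higher over every probe set. Without a pair the range was 0 to 306 lower and 0 to 326 higher. The block also gave 1 gene called in opposite directions in the mutants.

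Medians that changed sign with a call in either setting were all in abf1 ts, while lists without a call, such as RNA polymerases I and III or the iron regulon, changed sign in rap1 ts too. Meiosis and sporulation had 0.24 with no filter and 0.28 over every probe set, general stress -0.06 without wild-type array 1 and -0.11 without ts array 2, sulfur metabolism -0.12 without wild-type array 1 and -0.34 without ts array 3, and subtelomeric families -0.049 without wild-type array 3. The highest medians with an array left out were 0.43, 0.60 and 0.53 for these last 3 lists. Among called lists of rap1 ts the medians over all settings ran from -0.40 to -0.03 for cytosolic ribosomal proteins, 0.46 to 0.97 for mitochondrial ribosomal proteins, -0.54 to -0.07 for glycolysis, -0.47 to -0.11 for translation factors, 0.23 to 1.02 for heat shock, -0.55 to -0.19 for histones, -1.09 to -0.34 for the cell wall list and -0.44 to -0.02 for ergosterol. In abf1 ts they ran from -0.48 to -0.08 for mitochondrial ribosomal proteins, -0.37 to -0.08 for ribosome biogenesis, 0.12 to 0.40 for the cell wall list, 0.06 to 0.17 for amino acid biosynthesis and 0.03 to 0.26 for telomere-proximal genes. Apart from reversals, list medians had 1002 values on the same side of the test, 69 weaker and 42 stronger. Named genes called in rap1 ts that moved by over 1.5 times were TOS6 (-3.09 to -1.43), ENO1 (-3.15 to -1.30), ERG13 (-2.33 to -0.998), PHO5 (-1.83 to -0.91), RPL3 (-1.54 to -0.65), LEU2 (-2.19 to -0.59), PAU13 (-0.81 to -0.33), YPR148C (0.41 to 0.86), TDA6 (1.14 to 2.24) and HSP30 (1.12 to 3.06), and in abf1 ts DUG1 (-1.92 to -1.01). For named genes 1707 values stayed, 99 were weaker and 109 stronger. Beyond the calls given in the report, the cause of these moves was not tested.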

Other observations

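The neighbour test in rap1 ts, its control in the wild types and the tests without OPI3 and MOG1 were chosen only after the result was seen, since this pair had been noticed first. These 2 genes are transcribed away from each other from a shared upstream region, and both lay lower in rap1 ts (-3.84 and -2.54). CMI8 (1.75) had MRPL28 as its divergent neighbour at 1.28 (blocked adjusted p = 0.0131), and ARO10 (2.17) had SDH6 at 1.00 (blocked adjusted p = 0.0276). In abf1 ts NIT3 (-2.01) had LUG1 at 0.28 and DUG1 (-1.54) had MRX20 at 0.05, and neither neighbour passed. RPL3 (-1.20) and YHP1 (-2.27) had neighbours that moved the other way with the block in rap1 ts, YOR062C at 1.09 and PPN1 at 0.66. Of 19 named genes called with the block in rap1 ts that had a tested divergent neighbour, the neighbour passed in the same direction for 4, which count OPI3 and MOG1 each, in the other direction for 2 and not at all for 13. In abf1 ts it passed for 0 of 3. Of all 4687 features 470 fell and 701 rose in rap1 ts with the block, so some neighbours pass by chance. The counts of neighbours were not tested against that share. MRPL28 is also of the mitochondrial ribosomal list, in which 63 of 65 features lay above 0.

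A hypothesis of this re-analysis was that divergent neighbours share promoter regions that depend on each factor, so that their fold changes correlate more than those of convergent neighbours. In rap1 ts the correlation was 0.098 over 931 divergent pairs and -0.018 over 982 convergent pairs (1-sided permutation p = 0.0109, adjusted p = 0.0164). In abf1 ts it was 0.264 against 0.059 (permutation p = 1e-04, the smallest possible, adjusted p = 3e-04). Between the wild types it was 0.043 against 0.049 (permutation p = 0.552). Without the pair of OPI3 and MOG1, which prompted the hypothesis, the divergent correlation was 0.072 in rap1 ts (permutation p = 0.0203, adjusted p = 0.0304) and 0.263 in abf1 ts (permutation p = 1e-04). The correlations were above those of convergent neighbours in both mutants, weakly in rap1 ts, which does not show binding of either factor at any of these regions. The permutations shuffled gene pairs, which are not independent replicates, so these p-values do not measure the spread between arrays. Noise of the arrays that neighbouring genes share was not tested by other splits of the arrays.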
